A study of Mus musculus with 23 samples.

How the data were processed

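The values used are the deposited table of normalized counts, 1 column for each of the 23 libraries, treated as a signal in reads divided by 1 size factor per library. The submitters' processing notes name HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 2.11.40.6. Each deposited value is a whole number of reads over 1 factor per library, so the authors' values carry no correction for gene length. The notes name the builds mm10 and mm9 without a role for either, so no coordinates are given. RNA was extracted with Trizol and the RNeasy Micro kit, and libraries were made with the TruSeq RNA v2 kit from polyadenylated RNA, per the labels. All 23 value columns were used. In each library 100% of values were whole multiples of 1 step within a tolerance of 0.02 reads, so whole reads were recovered. Normalized totals were 21.5 to 25.2 M per library. Genes are called here by a model of log2 values, with tests of the recovered counts as alternatives.

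The table held 27606 entries, of which 428 were identical repeats and were removed, leaving 27178 genes. Of these 4174 were at 0 in all libraries and 958 had no symbol among 25274 Entrez identifiers of the reference. Genes with a normalized count of 10 or more in at least 5 libraries were tested, 16385 in all. Values were taken as log2 of the normalized count plus 1. A limma fit of 4 group means (R 4.3.3, limma 3.58.1, trended and robust empirical Bayes) gave 6 contrasts: the virus effect without stress, with stress and averaged over stress, the stress effect under each virus and the interaction. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Errors on group values are SD between libraries and errors on log2 fold changes are SE. Of 38 gene lists, with 840 symbols of which 826 were matched, 1 by a synonym, 37 had at least 5 tested members. The list of mitochondrially encoded genes matched no symbol and was not analysed here. Lists were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry. A list's level in a library is the mean of its members' centred log2 values, compared between groups by exact permutation and related to other levels with 100000 permutations.

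The groups, contrasts, lists, filter, threshold, alternatives and the rule for named genes were fixed before the data were examined. That rule takes Zbtb7a and a panel of Gfap, Slc1a2, Slc1a3, Glul, Aqp4, Nfkbia, Lcn2, Cxcl10 and C3. It adds up to 4 members by smallest p of each list past its test and, where fewer than 5 genes pass, the 5 genes of smallest p with a mean of 50 or more, given as values that did not pass. Some genes that the rule takes are not reported here. The lists named were a choice among those past camera. The alternatives fixed then were a pseudocount of 5, no filter, a mean of 50 or more, TMM scaling, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, empirical Bayes without the robust option, array weights, number run as a covariate, an adjusted p under 0.1, only the groups compared, an estimated correlation and each library left out. Covariates for the striatal level, for 3 tissue lists and for recovered reads, the fit without 5 libraries far in striatal level, and array weights for lists were added after the data were seen. In a self-test on counts simulated gene by gene, without correlation between genes, at these sizes, with 100 genes each changed 1.5-fold and 2-fold, limma recovered 67% and 92% for the virus effect without stress, 83% and 93% with stress, 67% and 87% for stress under GFP and 66% and 92% under ZBTB7A. It made 12, 9, 6 and 7 false calls, and camera called the changed list in each and 0 others. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.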

Results

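Bulk RNA-seq of polyadenylated RNA was collected in 23 libraries from the orbitofrontal cortex (OFC) of male C57BL/6J mice. Per the labels, mice (age given as 8 weeks) received an AAV6 vector on day 0 that carried ZBTB7A, a zinc-finger transcription factor, or GFP behind the promoter of the astrocyte gene Gfap. A subthreshold social defeat stress, a brief exposure to an aggressor, followed on day 21 in some mice, while the others were unstressed controls. Tests of social interaction, sucrose preference and forced swimming ran from day 22 to day 27, and virally infected OFC tissue was microdissected on day 28. The groups were GFP control (n = 5), GFP stress (n = 8), ZBTB7A control (n = 5) and ZBTB7A stress (n = 5). Libraries are named here by group and by the number in their title. No number is shared between groups, so no library could be paired. The labels do not say that no mouse gave more than 1 library, so p-values measure the spread between samples. Camera p-values instead compare list members with other genes.

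Recovered reads came to 12.5 to 51.9 M per library. Their mean ± SD was 25.5 ± 8.48 M in GFP control, 22.9 ± 14 M in GFP stress, 24.5 ± 13.9 M in ZBTB7A control and 30.2 ± 13.4 M in ZBTB7A stress. Between 18536 and 20238 genes had a value above 0 in a library. Pairwise correlations of log2 values ranged from 0.944 to 0.993, with a median of 0.983 within groups and 0.982 between groups, across genes, which are not independent replicates. The numbers in the titles pass through the 4 groups in order 3 times, in runs of 8, 7 and 8 libraries, and group differences are also given within these runs. Fits were repeated with covariates for number run, the striatal level or 3 tissue levels (striatal, olfactory bulb and choroid plexus lists). A fit without 5 far libraries, the farthest from the median striatal level, lost GFP stress 5, 12, 20 and 21 and ZBTB7A control 6. Its smaller groups may also end calls. The level of striatal neuron genes, which mark the medium spiny neurons of a neighbouring region, spread widely within groups. Its mean ± SD was 0.53 ± 0.52 in GFP control, -0.99 ± 1.43 in GFP stress, 0.12 ± 1.16 in ZBTB7A control and 0.93 ± 0.61 in ZBTB7A stress.

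Zbtb7a (Entrez 16969), the mouse gene of the name given for the vector, was not raised in the libraries labelled ZBTB7A. Its normalized count was 3834 ± 629 (SD, n = 5) in GFP control, 3934 ± 251 (n = 8) in GFP stress, 3716 ± 247 (n = 5) in ZBTB7A control and 3744 ± 173 (n = 5) in ZBTB7A stress. Averaged over stress, the fold between viruses was 0.965 with a 95% interval of 0.890 to 1.05. The log2 difference was -0.03 without stress (exact two-sided permutation p = 0.802, n = 5 and 5) and -0.07 with stress (exact permutation p = 0.161, n = 5 and 8). Without stress its sign turned when GFP control 10, GFP control 11 or ZBTB7A control 24 was left out, with values between -0.11 and 0.04 over all left-out libraries. Within the number runs the difference was 0.24, -0.18 and -0.12 without stress and -0.02, -0.19 and -0.05 with stress. Stress gave log2 differences of 0.05 under GFP (exact permutation p = 0.606, n = 8 and 5) and 0.01 under ZBTB7A (exact permutation p = 0.849, n = 5 and 5). Leaving out GFP control 1 turned the first of these to -0.03, and the sign of the other turned without ZBTB7A control 23 or 24 or ZBTB7A stress 7 or 9. The interaction for Zbtb7a was -0.04 ± 0.11 (log2, SE), and 0.04 without GFP control 1. With 3 tissue levels, Zbtb7a turned to -0.03 for stress under GFP and to 0.04 for the interaction.

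Gfap, the astrocyte intermediate filament whose promoter drives the vector, varied 9.29-fold between libraries, from 2839.7 to 26388 normalized counts. Group values were 11492 ± 8694 in GFP control, 6819 ± 3293 in GFP stress, 11907 ± 5436 in ZBTB7A control and 11949.9 ± 5188 in ZBTB7A stress (SD, n = 5, 8, 5 and 5). Under stress the libraries labelled ZBTB7A stood above GFP by 0.86 ± 0.41 on the log2 scale, a fold of 1.81 with a 95% interval of 1.00 to 3.27. That difference had an exact permutation p = 0.0591 (n = 5 and 8) and was 0.85, 1.78 and 0.38 within the number runs. The log2 difference for Gfap was 0.19 between viruses without stress (exact permutation p = 0.738, n = 5 and 5), -0.63 for stress under GFP (exact permutation p = 0.213, n = 8 and 5) and 0.03 for stress under ZBTB7A (exact permutation p = 0.944, n = 5 and 5). Without stress, leaving out GFP control 11 turned the virus difference of Gfap to -0.09. Under ZBTB7A the sign of the stress difference turned without ZBTB7A control 23 or 24 or ZBTB7A stress 9 or 17, and with the striatal level (-0.16) or 3 tissue levels (-0.07).

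**Figure D1:**
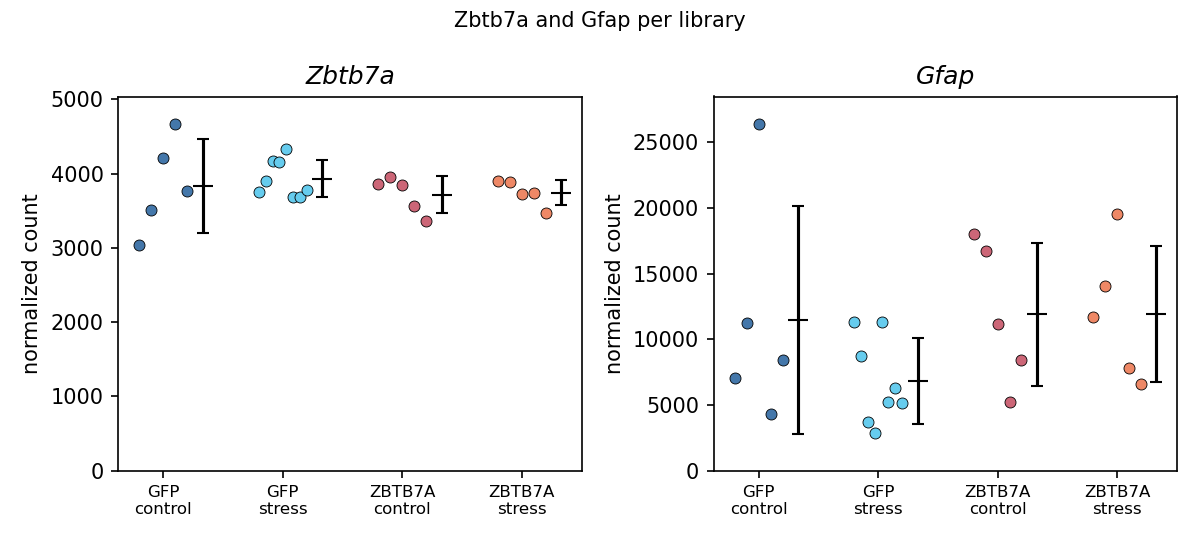
Normalized count of Zbtb7a and Gfap in each library (points) of GFP control (n = 5), GFP stress (n = 8), ZBTB7A control (n = 5) and ZBTB7A stress (n = 5), with bars for mean ± SD. Zbtb7a lies between 3033 and 4666 in all 23 libraries, while Gfap runs from 2839.7 to 26388.

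Without stress, the comparison of ZBTB7A control with GFP control (n = 5 each) asks what the vector alone did to OFC gene expression. Choroid plexus and ependymal genes, which mark cells that line the ventricles, were lower in ZBTB7A control, with a mean log2 fold change of -1.30 and 13 of 14 members below 0. Among them Kl, a co-receptor for fibroblast growth factors, stood at 62.1 ± 28.4 against 163 ± 95.6 normalized counts. The transcription factor Otx2 had a log2 fold change of -2.36 ± 0.88 (SE), the chloride channel protein Clic6 of -1.89 ± 0.70 and the secreted antagonist Sostdc1 of -1.70 ± 0.50. The list passed camera (adjusted p = 6.1e-12 and adjusted p = 0.278 with an estimated correlation), and 5 of its members passed when adjusted over the list alone. Its level differed between the groups with an exact permutation p = 0.103 (n = 5 and 5; adjusted over 37 lists, 0.910), and within the number runs by -0.32, -1.84 and -0.49.

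Genes of the astrocyte panel did not separate the unstressed groups. The log2 fold changes (SE) were 0.06 ± 0.07 for Slc1a2 and 0.03 ± 0.10 for Slc1a3, both glutamate transporters, -0.10 ± 0.09 for Glul, the glutamine synthetase, and -0.14 ± 0.19 for the water channel Aqp4. They were -0.24 ± 0.17 for Nfkbia, the inhibitor of NF-kB, 0.79 ± 1.34 for the secreted lipocalin Lcn2, 0.99 ± 0.71 for the chemokine Cxcl10 and 0.44 ± 1.14 for complement C3. Leaving out GFP control 11 turned Slc1a3 to -0.07 and C3 to -0.37, and C3 also turned to -0.12 without ZBTB7A control 14. With edgeR and DESeq2 both Lcn2 and C3 turned, to -0.12 and -0.36 in edgeR, and with array weights Gfap, Slc1a3 and C3 did. Homeostatic astrocyte genes, with Kcnj10, a potassium channel, at -0.19, had a mean of -0.07 (21 of 30 below 0, camera adjusted p = 0.0496 and adjusted p = 0.742 with an estimated correlation). That call ended without GFP control 1, 2 or 10, GFP stress 5, ZBTB7A control 14, 15, 23 or 24 or ZBTB7A stress 9 or 25. It also ended with number run (-0.05), and with 3 tissue levels the list turned to 0.02 and Aqp4 to 0.09.

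Metabolic, stress-hormone and myelin genes were lower under ZBTB7A by camera. Oxidative phosphorylation genes, with the cytochrome c oxidase subunit Cox5a at -0.22, averaged -0.07 (35 of 37 below 0, camera adjusted p = 1.0e-04 and adjusted p = 0.589 with an estimated correlation), within the number runs -0.08, -0.03 and -0.11, and -0.10 without GFP control 10. Cholesterol synthesis genes, with the pathway enzymes Pmvk at -0.17 and Msmo1 at -0.15, averaged -0.10 (22 of 23 below 0, camera adjusted p = 1.7e-04 and adjusted p = 0.589 with an estimated correlation), a difference that vanished without ZBTB7A control 6 (6.3e-04) and turned with array weights (0.05). Glucocorticoid-induced genes, with the leucine zipper protein Tsc22d3 at -0.29 and the kinase Sgk1 at -0.37, averaged -0.14 (16 of 20 below 0, camera adjusted p = 0.00373 and adjusted p = 0.589 with an estimated correlation). Their call ended without GFP control 2 (-0.01) or ZBTB7A control 15 (-0.10), and the mean was -0.22 without ZBTB7A control 6 and -0.04 with 3 tissue levels, where the direction by camera turned. Oligodendrocyte and myelin genes, with the phospholipase Enpp2 at -0.30, averaged -0.28 (24 of 24 below 0, camera adjusted p = 2.9e-04 and adjusted p = 0.661 with an estimated correlation) but 0.51, -0.62 and -0.03 within the number runs. Their call ended without GFP control 10 (-0.06) or ZBTB7A control 23 (-0.11), and the mean was -0.49 without ZBTB7A control 6. The list turned with 3 tissue levels, to 0.26, and Enpp2 to 0.07.

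Immediate early genes, the rapid transcriptional response to neuronal activity, were higher in ZBTB7A control, with a mean of 0.15 and 18 of 24 members above 0 (camera adjusted p = 3.8e-04 and adjusted p = 0.589 with an estimated correlation). Btg2, an antiproliferative member, was at 0.62 ± 0.21 and the activity-dependent transcription factor Npas4 at 0.46 ± 0.27. The means within number runs were 0.30, -0.32 and 0.59, the call ended without GFP control 2 (0.08), and the mean was 0.10 without GFP control 19, 0.24 without ZBTB7A control 15 and 0.08 without ZBTB7A control 23. Microglia genes averaged 0.11 (22 of 25 above 0, camera adjusted p = 6.1e-04 and adjusted p = 0.609 with an estimated correlation). That call ended without GFP control 11 or ZBTB7A control 6 or 14, and the mean was 0.24 without GFP control 10 and 0.19 without ZBTB7A control 24. With array weights the direction turned (-0.04). Blood genes averaged 0.94 (4 of 5 above 0, camera adjusted p = 0.00382 and adjusted p = 0.589 with an estimated correlation), with the heme enzyme Alas2 at 1.31 and the globin Hba-a2 at 1.12, but -0.14, -0.01 and 2.57 within runs. The blood call ended without GFP control 11 (0.94) or ZBTB7A control 23 (0.27). Antigen presentation genes, with the peptide transporter Tap1 at 0.39, averaged 0.12 (camera adjusted p = 0.00382 and adjusted p = 0.589 with an estimated correlation). The call ended without GFP control 1 or 11 or ZBTB7A control 6 or 23, and the mean was 0.24 without GFP control 10 and 0.21 without ZBTB7A control 15.

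Other lists were also lower under ZBTB7A by camera. Inhibitory neuron genes, with the GABA-synthesizing enzyme Gad2 at -0.30 and somatostatin, Sst, at -0.18, averaged -0.14 (18 of 21 below 0, camera adjusted p = 0.0367 and adjusted p = 0.589 with an estimated correlation). This call ended without GFP control 1, 2, 11 or 19 or ZBTB7A control 6 or 23. Cytosolic ribosomal protein genes averaged -0.06 (camera adjusted p = 0.00467 and adjusted p = 0.742 with an estimated correlation). This list call ended without GFP control 1 or 2 or ZBTB7A control 15. It also ended with number run (-0.04) and turned to 0.06 with 3 tissue levels. Heat shock and unfolded protein response genes, with the chaperone Hspa5 at -0.12 and the endoplasmic reticulum protein Herpud1 at -0.16, averaged -0.04 (camera adjusted p = 0.0424 and adjusted p = 0.589 with an estimated correlation). The list call ended without GFP control 1, 10 or 19 or ZBTB7A control 6. Among genes with a mean normalized count of 50 or more, from which the genes with the smallest p are taken in each comparison, these were Stk32b, a kinase (46.0 ± 4.94 against 75.7 ± 19.7 normalized counts), Kl, the apoptosis regulators Bad (382 ± 24.8 against 442 ± 31.4) and Bok (763 ± 41.9 against 972 ± 79.2), and Rgs16, a regulator of G-protein signalling (278 ± 24.4 against 338 ± 34.3), and none passed. No gene passed limma (0 of 16385), and edgeR, DESeq2 and limma with array weights also called 0. At an unadjusted p under 0.05 there were 284 genes, 121 higher and 163 lower, where 819 were due by chance. Their number was 664 without GFP control 11 and 1038 without ZBTB7A control 6. By exact permutation, 0 of 37 list levels had p under 0.05 (virus with stress 9, stress with GFP 4, with ZBTB7A 1). Camera passed 20, 8 higher and 12 lower, 0 with an estimated correlation, 12 without GFP control 2 and 13 without ZBTB7A control 23. Of the 20 calls, 4 with the striatal level, 5 with 3 tissue levels, 7 without 5 far libraries and 8 with array weights ended or turned. The homeostatic and ribosomal calls ended with the striatal level, and the microglia, antigen, inhibitory and heat shock calls without 5 far libraries.

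The comparison of ZBTB7A stress (n = 5) with GFP stress (n = 8) gives the virus difference in stressed mice, including any present without stress. Astrocyte reactivity genes were higher in ZBTB7A stress, with a mean log2 fold change of 0.82 and 13 of 13 members above 0. Serpina3n, a protease inhibitor of reactive astrocytes, stood at 1863 ± 1064 against 903 ± 377 normalized counts, and the metalloreductase Steap4 at 197 ± 252 against 35.7 ± 29.0. The log2 fold changes (SE) of the cytokine receptor Osmr, 0.59 ± 0.25, the ferroxidase Cp, 0.53 ± 0.23, Lcn2, 1.98 ± 1.20, and Cxcl10, 1.29 ± 0.64, had the same sign. The list passed camera (adjusted p = 0.00122 and adjusted p = 0.528 with an estimated correlation), and its level differed with an exact permutation p = 0.0373 (n = 5 and 8; adjusted over 37 lists, 0.180). Within the number runs the level differed by 0.53, 1.74 and 0.69. Without ZBTB7A stress 17, in which Lcn2 reached 1761 and C3 4438 normalized counts, the mean was 0.52 and the call ended (adjusted p = 0.0551 by camera).

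The same library carried other immune and reactive lists. LPS-type (A1) reactive astrocyte genes averaged 0.41 (11 of 12 above 0, camera adjusted p = 0.00879 and adjusted p = 0.528 with an estimated correlation), with the elastic fibre protein Fbln5 at 0.52, the glycosyltransferase Ggta1 at 0.59 and C3 at 1.93. Activated microglia genes averaged 0.50 (19 of 20 above 0, camera adjusted p = 0.00235 and adjusted p = 0.618 with an estimated correlation), with the lipase Lpl at 0.78 and the cholesterol hydroxylase Ch25h at 0.95. Microglia genes averaged 0.20 (23 of 25 above 0, camera adjusted p = 0.00536 and adjusted p = 0.625 with an estimated correlation). NF-kB pathway and target genes averaged 0.24 (21 of 26 above 0, camera adjusted p = 0.0106 and adjusted p = 0.618 with an estimated correlation), with the adhesion molecule Vcam1 at 0.37, the innate receptor Tlr2 at 0.66 and Nfkbia at 0.15 (-0.03 with 3 tissue levels). Extracellular matrix and scar genes averaged 0.29 (18 of 25 above 0, camera adjusted p = 0.00549 and adjusted p = 0.528 with an estimated correlation), and 5 passed when adjusted over the list alone, among them the laminin chain Lamb1 (0.57 ± 0.14) and the integrin Itga5 (1.11 ± 0.30). All these calls ended without ZBTB7A stress 17. Complement genes, with C4b at 0.95, averaged 0.35 (14 of 18 above 0, camera adjusted p = 0.0337 and adjusted p = 0.625 with an estimated correlation). The list no longer passed without GFP stress 5, 21 or 22 or ZBTB7A stress 17. Of these lists all but the extracellular matrix one also ended with the striatal level, with 3 tissue levels and without 5 far libraries. Slc1a2 (0.03 ± 0.07), Slc1a3 (0.10 ± 0.09), Glul (-0.04 ± 0.08) and Aqp4 (0.17 ± 0.17), which serve glutamate and water handling in astrocytes, did not pass.

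Genes of excitatory neurons and of synaptic vesicles were lower in ZBTB7A stress. Nrgn, a postsynaptic calmodulin-binding protein, stood at 33188 ± 6508 against 50408 ± 7658 normalized counts, and the neuropeptide Cck at 4095 ± 1144 against 6609.8 ± 1341. Excitatory neuron genes averaged -0.22 with 16 of 20 members below 0 (camera adjusted p = 0.00744 and adjusted p = 0.528 with an estimated correlation). Their level differed with an exact permutation p = 0.00311 (n = 5 and 8; adjusted over 37 lists, 0.109) and by -0.37, -0.06 and -0.15 within the number runs. Foxp2 (0.85 ± 0.25), a transcription factor, and Arpp21 (0.46 ± 0.15), a phosphoprotein, went the other way, and both are also known in striatal neurons. They were among 4 members that passed when adjusted over the list alone. Presynaptic vesicle genes averaged -0.20 with 24 of 26 below 0 (camera adjusted p = 1.2e-05 and adjusted p = 0.528 with an estimated correlation, exact permutation p = 0.0101, or 0.109 adjusted over 37 lists), and -0.32, -0.10 and -0.13 within runs. Its members of the vesicle fusion machinery included Snap25 (-0.38 ± 0.15), Stx1a (-0.55 ± 0.21), Vamp1 (-0.50 ± 0.17) and Rab3a (-0.25 ± 0.09). Immediate early genes averaged -0.22 (22 of 24 below 0, camera adjusted p = 0.00157 and adjusted p = 0.528 with an estimated correlation) and -0.35, -0.41 and 0.0099 within runs, with the neurotrophin Bdnf at -0.59, the phosphatase Dusp6 at -0.49 and the synaptic pentraxin Nptx2 at -0.32. Postsynaptic density genes, with the kinase Camk2a at -0.28, averaged -0.09 (camera adjusted p = 0.0245 and adjusted p = 0.618 with an estimated correlation). The list failed camera without GFP stress 5 or 13 or ZBTB7A stress 9. The excitatory list turned with 3 tissue levels to 0.05, the presynaptic list to 0.05 (0.0067 with the striatal level) and the postsynaptic list by camera (-9.7e-05), as did Snap25, Stx1a, Camk2a, Bdnf and Nptx2. With the striatal level the excitatory (0.0027), immediate early (-0.09) and postsynaptic (-0.04) calls ended. The last 2 also ended without 5 far libraries, and the immediate early call with 3 tissue levels.

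Of neighbouring tissue, striatal neuron genes were higher in ZBTB7A stress in 17 of 17 members (mean 1.92). Olfactory bulb (-0.24) and meningeal (-0.03) genes were not. The neuropeptide gene Penk stood at 11652 ± 4831 against 3961 ± 2896, the phosphodiesterase Pde10a at 12792 ± 4393 against 4906 ± 3658, the retinoic acid receptor Rarb at 1110.3 ± 344 against 434 ± 271 and the transcription factor Isl1 at 131 ± 77.4 against 25.2 ± 26.7. The striatal list passed camera (adjusted p = 4.3e-13, and 0.528 with an estimated correlation), and 17 members passed when adjusted over the list alone. Its level differed with an exact permutation p = 0.0140 (n = 5 and 8; adjusted over 37 lists, 0.109) and by 2.08, 1.07 and 2.20 within the number runs. Choroid plexus and ependymal genes, with Clic6 at 1.95 and Otx2 at 2.0, averaged 0.96 (12 of 14 above 0, camera adjusted p = 0.00162 and adjusted p = 0.528 with an estimated correlation) and 1.39, 1.12 and 0.44 within runs. Oligodendrocyte and myelin genes, among them the myelin protein genes Mal (0.73) and Opalin (0.71) and transferrin, Trf (0.73), averaged 0.57 (24 of 24 above 0, camera adjusted p = 1.3e-06 and adjusted p = 0.528 with an estimated correlation) and 0.85, 0.10 and 0.56 within runs. Oligodendrocyte precursor genes, with the proteoglycan Vcan at 0.62 ± 0.16 and the lineage factor Olig2 at 0.37 ± 0.18, averaged 0.29 (13 of 14 above 0, camera adjusted p = 0.00106 and adjusted p = 0.528 with an estimated correlation), and Vcan alone passed when adjusted over the list alone. The oligodendrocyte list turned with the striatal level (-0.05) and with 3 tissue levels (-0.13), as did Mal, Trf, Opalin and Olig2 with the latter, and its call ended without 5 far libraries. The choroid plexus (0.28) and precursor (0.08) calls ended with the striatal level, and the latter with 3 tissue levels.

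Metabolic genes were lower in ZBTB7A stress by small amounts. Cholesterol synthesis genes, with Mvd at -0.34 ± 0.11, averaged -0.14 (22 of 23 below 0, camera adjusted p = 4.2e-05 and adjusted p = 0.528 with an estimated correlation, exact permutation p = 0.0389, or 0.180 adjusted over 37 lists) and -0.22, -0.28 and 0.01 within runs. Oxidative phosphorylation genes, with the respiratory chain subunits Cox7b at -0.21 and Cyc1 at -0.13, averaged -0.09 (33 of 37 below 0, camera adjusted p = 1.2e-05 and adjusted p = 0.528 with an estimated correlation) and -0.05, -0.04 and -0.18 within runs. Glycolysis genes averaged -0.04 (19 of 23 below 0, camera adjusted p = 0.00536 and adjusted p = 0.528 with an estimated correlation). Cell cycle genes averaged 0.44 (23 of 24 above 0, camera adjusted p = 0.00235 and adjusted p = 0.625 with an estimated correlation), with 0.66 without GFP stress 13, but turned with the striatal level (-0.15), with 3 tissue levels (-0.20) and without 5 far libraries (-0.04). Blood genes, with Hba-a2 at -0.96 and the red cell anion exchanger Slc4a1 at -2.51, averaged -1.06 (camera adjusted p = 0.0186 and adjusted p = 0.528 with an estimated correlation), with -0.77, -3.24 and 0.12 within runs. Their call ended without GFP stress 13 (-0.68). Endothelial and mural cell genes, with the contractile genes Acta2 at 0.62 and Tagln at 0.48, averaged 0.12 (camera adjusted p = 0.0227 and adjusted p = 0.625 with an estimated correlation). That call ended without GFP stress 3, 4 or 22 or ZBTB7A stress 25 or 26. Cytosolic ribosomal protein genes averaged 0.05 (camera adjusted p = 0.0296 and adjusted p = 0.807 with an estimated correlation). The call ended without GFP stress 5, 12 or 20 or ZBTB7A stress 7 or 9. It turned with the striatal level (-0.08), with 3 tissue levels (-0.11) and without 5 far libraries (-0.0090). Heat shock and unfolded protein response genes averaged -0.02 (camera adjusted p = 0.0290 and adjusted p = 0.547 with an estimated correlation). This call ended without GFP stress 4 or 5 or ZBTB7A stress 7. With the striatal level the cholesterol (-0.02), glycolysis (-0.03), blood (-0.85) and heat shock (0.01) calls ended, all but the blood call also with 3 tissue levels.

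The smallest p in this comparison belonged to Cartpt (Entrez 27220), a neuropeptide precursor, at 352 ± 104 against 133 ± 53.4 normalized counts, a fold of 2.72 with a 95% interval of 1.85 to 4.01 (limma adjusted p = 0.183). Next came the axon guidance cue Ntn1 (566 ± 134 against 302 ± 96.6), the protocadherin Pcdhb16 (0.39 ± 0.08, log2 and SE), the nucleolar protein Rrp1b (0.45 ± 0.09) and the mineralocorticoid receptor Nr3c2 (0.39 ± 0.08). No gene passed limma (0 of 16385), while 2635 genes had an unadjusted p under 0.05, 1496 higher and 1139 lower, against 819 due by chance. Their number was 1458 without ZBTB7A stress 9. edgeR called 0 genes, DESeq2 81 and limma with array weights 2287. A fit of the compared groups alone called 2, Fxyd7 (-0.47) and Basp1 (-0.37), and leaving out GFP stress 13 called 3, Ntn1, Ptpn13 (0.41) and Baz1a (0.76). All of these but Ntn1 are named here only because these fits called them. Of 37 lists 23 passed camera, 14 higher and 9 lower, and 0 did with an estimated correlation. Of the 23 calls, 18 with the striatal level, 16 with 3 tissue levels, 11 without 5 far libraries and 2 with array weights ended or turned. The calls that remained with the striatal level were of reactive astrocyte, endothelial, oxidative phosphorylation and extracellular matrix genes.

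**Figure D2:**
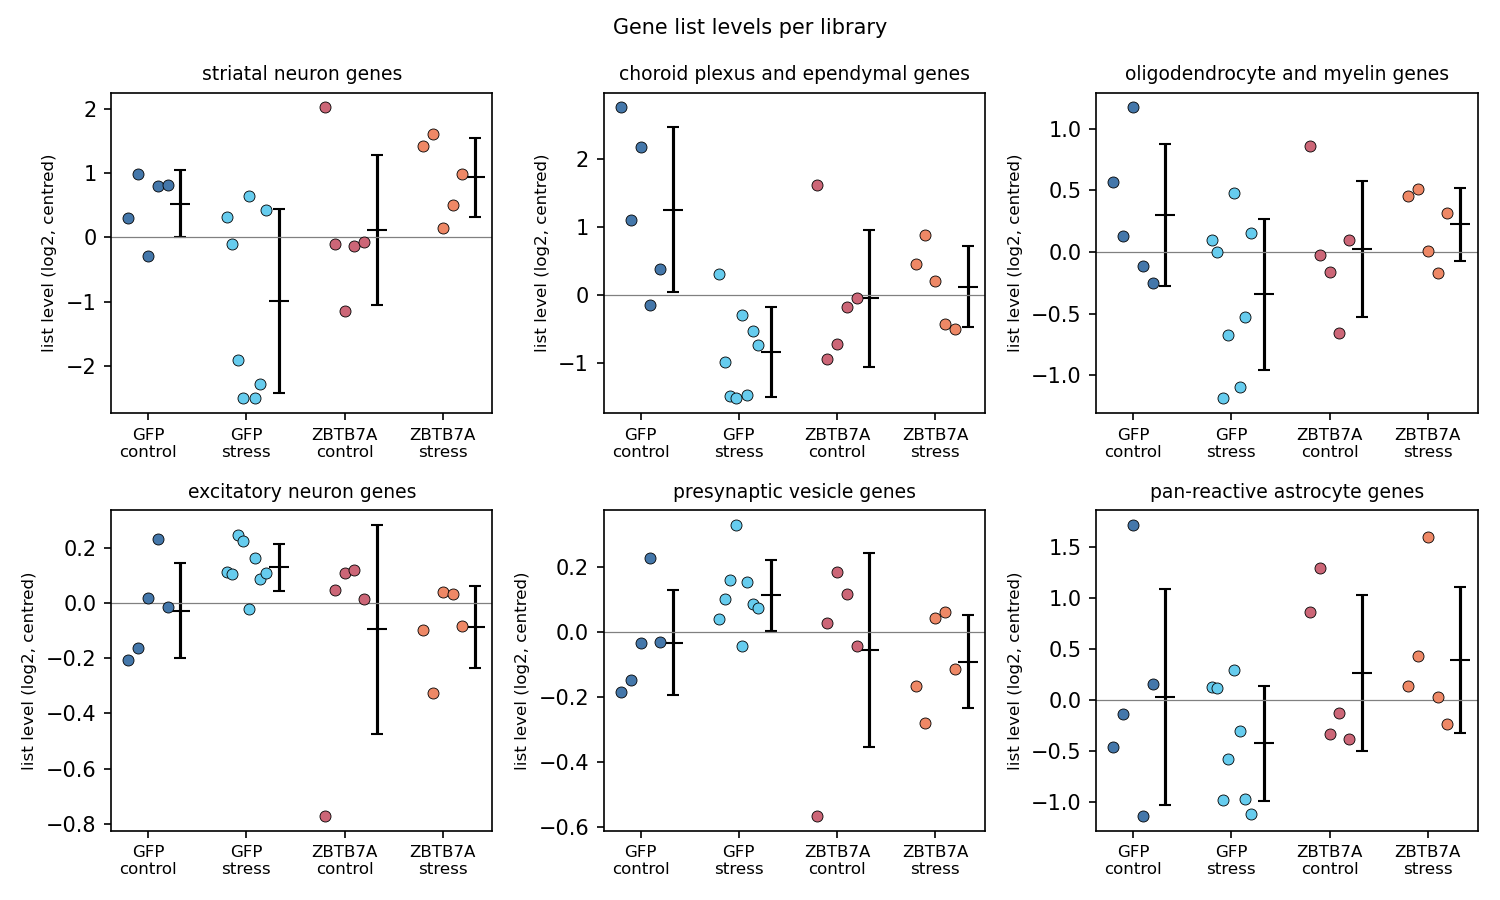
Level of 6 gene lists in each library (points), as the mean of centred log2 values of the members, in GFP control (n = 5), GFP stress (n = 8), ZBTB7A control (n = 5) and ZBTB7A stress (n = 5), with bars for mean ± SD. Striatal neuron genes average -0.99 ± 1.43 in GFP stress and 0.93 ± 0.61 in ZBTB7A stress, and choroid plexus and ependymal genes 1.25 ± 1.21 in GFP control and -0.83 ± 0.66 in GFP stress.

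Averaged over stress, the virus effect sets libraries labelled ZBTB7A (n = 10) against GFP (n = 13), which does not show that both stress conditions share it. Bok, an apoptosis regulator of the endoplasmic reticulum, stood at 763 ± 41.9 and 792 ± 122 normalized counts in ZBTB7A control and stress against 972 ± 79.2 and 992 ± 127 under GFP, a fold of 0.791 (limma adjusted p = 0.611). Other genes with the smallest p were also lower, among them Bad (-0.18 ± 0.04, log2 and SE), Tmem160 (-0.24 ± 0.05), Hcfc1r1 (-0.16 ± 0.04) and Coprs (-0.27 ± 0.06), and none passed. Astrocyte reactivity genes averaged 0.53 with 13 of 13 members above 0 (camera adjusted p = 2.0e-04 and adjusted p = 0.617 with an estimated correlation), including Cxcl10 at 1.14 ± 0.48, Gfap at 0.52 ± 0.31 and Serpina3n at 0.65 ± 0.35. Their mean was 0.23 without and 0.82 with stress. Microglia genes averaged 0.15 (24 of 25 above 0, camera adjusted p = 2.0e-05 and adjusted p = 0.617 with an estimated correlation), with 0.10 without GFP control 11. NF-kB pathway and target genes averaged 0.16 (21 of 26 above 0, camera adjusted p = 0.00662 and adjusted p = 0.617 with an estimated correlation). This list call ended without GFP control 1 or 11 or ZBTB7A stress 17 and was 0.25 without GFP control 10.

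Cholesterol synthesis genes were lower under ZBTB7A in 23 of 23 members, by a mean of -0.12 (camera adjusted p = 1.2e-08 and adjusted p = 0.617 with an estimated correlation), with Pmvk at -0.18 ± 0.05 and Msmo1 at -0.15 ± 0.05. Oxidative phosphorylation genes averaged -0.08 (34 of 37 below 0, camera adjusted p = 3.1e-09 and adjusted p = 0.617 with an estimated correlation), with Cox5a at -0.21 ± 0.07. Presynaptic vesicle genes averaged -0.11 (23 of 26 below 0, camera adjusted p = 1.3e-04 and adjusted p = 0.617 with an estimated correlation), with Vamp1 at -0.38 and Snap25 at -0.24, from -0.02 without and -0.20 with stress. Without ZBTB7A control 6 the presynaptic call ended (-0.05), and the cholesterol mean was -0.07. Heat shock and unfolded protein response genes averaged -0.03 (24 of 28 below 0, camera adjusted p = 0.00385 and adjusted p = 0.617 with an estimated correlation), -0.02 without ZBTB7A control 6, and Herpud1 (-0.14 ± 0.04) was the 1 member that passed when adjusted over the list alone. limma called 0 of 16385 genes and edgeR 0, with 994 at an unadjusted p under 0.05 (1561 without GFP stress 13). DESeq2 called 7, among them Bok, Tmem160, Coprs and Hcfc1r1. Camera passed 17 of 37 lists, 11 higher and 6 lower, and 0 with an estimated correlation. Of these calls, 5 with the striatal level, 2 with 3 tissue levels, 14 without 5 far libraries and 3 with array weights ended or turned. Those of the presynaptic and heat shock lists ended with the striatal level, and without 5 far libraries every list named here ended but cholesterol synthesis and oxidative phosphorylation.

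Stress under the GFP vector (GFP stress, n = 8, against GFP control, n = 5) compares stressed with unstressed mice that did not receive the ZBTB7A vector. Choroid plexus and ependymal genes were lower after stress by a mean log2 fold change of -2.09, with 13 of 14 members below 0. Ttr, the thyroid hormone carrier of the choroid plexus, stood at 130.1 ± 235 against 2747 ± 3326 normalized counts, Clic6 at 48.2 ± 36.6 against 238 ± 113 and the folate receptor Folr1 at 4.46 ± 2.07 against 38.6 ± 35.6. The list passed camera (adjusted p = 1.1e-12 by camera and adjusted p = 0.228 with an estimated correlation) and also fry (false discovery rate 0.0181), and 12 members passed when adjusted over the list alone. Its level differed with an exact permutation p = 0.00155 (n = 8 and 5; adjusted over 37 lists, 0.0575) and by -2.65, -1.91 and -1.29 within the number runs. Striatal neuron genes were lower in 17 of 17 members, by -1.51 (camera adjusted p = 7.2e-10 and adjusted p = 0.653 with an estimated correlation, exact permutation p = 0.0474, or 0.407 adjusted over 37 lists), and by -1.20, -1.19 and -2.28 within runs. Of these, 9 passed when adjusted over the list alone, with Isl1 at -3.31 ± 0.89 and the dopamine receptor Drd2 at -2.29 ± 0.87.

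Glial genes were lower after stress under GFP. Oligodendrocyte and myelin genes, with Mal at -0.75, averaged -0.64 (24 of 24 below 0, camera adjusted p = 8.4e-11 and adjusted p = 0.653 with an estimated correlation) and -0.71, -0.63 and -0.24 within runs, with -0.43 without GFP control 10. Oligodendrocyte precursor genes, with the growth factor receptor Pdgfra at -0.24 ± 0.07 and Vcan at -0.59 ± 0.16, averaged -0.33 (13 of 14 below 0, camera adjusted p = 1.3e-05 and adjusted p = 0.580 with an estimated correlation, exact permutation p = 0.0140, or 0.220 adjusted over 37 lists), and 2 members passed when adjusted over the list alone. Astrocyte reactivity genes averaged -0.45 (13 of 13 below 0, camera adjusted p = 0.0225 and adjusted p = 0.694 with an estimated correlation), with Cp at -0.59 and Gfap at -0.63, and Aqp4 was at -0.36 ± 0.17. This call ended without GFP control 10 (-0.03) or GFP stress 22 (-0.36), the mean was -0.74 without GFP control 11, and within runs it was 0.05, -0.43 and -0.95. LPS-type (A1) reactive astrocyte genes averaged -0.39 (11 of 12 below 0, camera adjusted p = 0.0105 and adjusted p = 0.653 with an estimated correlation), with Fbln5 at -0.61 ± 0.17, the 1 member that passed when adjusted over the list alone. Complement genes averaged -0.35 (17 of 18 below 0, camera adjusted p = 0.0178 and adjusted p = 0.694 with an estimated correlation), with C4b at -0.89. The A1 call ended without GFP control 10 (-0.23) and the complement call without GFP control 10 (-0.12) or GFP stress 22 (-0.29). NF-kB pathway and target genes, with the adaptor Traf1 at -1.0, averaged -0.17 (camera adjusted p = 0.0318 and adjusted p = 0.694 with an estimated correlation). The list call ended without GFP control 10 or GFP stress 5, 21 or 22, and the mean was -0.27 without GFP control 11. Extracellular matrix and scar genes averaged -0.21 (camera adjusted p = 0.0237 and adjusted p = 0.694 with an estimated correlation), with 1 member past when adjusted over the list alone. The list no longer passed without GFP control 10 or 11 or GFP stress 12 or 22. All these calls but that of precursor genes ended with the striatal level and without 5 far libraries. With number run the reactive astrocyte (-0.32), NF-kB (-0.13), complement (-0.26) and extracellular matrix (-0.18) calls ended. With 3 tissue levels the lists turned for oligodendrocytes (0.39), their precursors by camera (-0.0075), reactive (0.27) and A1 (0.04) astrocytes, NF-kB (0.15) and complement (0.09), as did Mal, C4b and Gfap.

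Immediate early, synaptic vesicle, postsynaptic and excitatory neuron genes were higher after stress under GFP. Immediate early genes averaged 0.24 with 22 of 24 members above 0 (camera adjusted p = 6.0e-05 and adjusted p = 0.653 with an estimated correlation) and 0.45, 0.06 and 0.31 within runs. Npas4 stood at 610.0 ± 165 against 391 ± 161 normalized counts, Nptx2 at 1422 ± 232 against 1062 ± 209.6 and Btg2 at 623 ± 109 against 448 ± 178. Presynaptic vesicle genes averaged 0.15 (24 of 26 above 0, camera adjusted p = 5.1e-05 and adjusted p = 0.694 with an estimated correlation) and 0.27, 0.05 and 0.14 within runs, with the synaptic vesicle protein Syp at 0.23. Excitatory neuron genes, with Nrgn at 0.42 and the deep-layer factor Fezf2 at 0.49, averaged 0.16 (15 of 20 above 0, camera adjusted p = 0.0156 and adjusted p = 0.694 with an estimated correlation) and 0.34, -0.02 and 0.14 within runs. The list failed camera without GFP control 1 (0.11). Postsynaptic density genes averaged 0.07 (camera adjusted p = 0.0157 and adjusted p = 0.694 with an estimated correlation), with 0.14 without GFP control 11. Their call ended without GFP control 1 (-0.01) or GFP stress 5 (0.04). Oxidative phosphorylation genes averaged 0.06 (33 of 37 above 0, camera adjusted p = 5.1e-05 and adjusted p = 0.694 with an estimated correlation). That call ended without GFP control 10 (0.03). With 3 tissue levels, these directions turned for the excitatory (-0.23), presynaptic (-0.21) and postsynaptic (-0.13) lists and for Nrgn, Fezf2 and Syp. These 3 list calls ended with the striatal level, and the postsynaptic and immediate early calls did without 5 far libraries.

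Besides Ttr, the genes with the smallest p after stress under GFP were the ion channel Trpm3 (573 ± 54.7 against 956 ± 295 normalized counts), the orphan receptor Gpr101 (26.9 ± 13.6 against 187 ± 200.1), the matrix protein Frem2 (82.2 ± 18 against 133 ± 11.8) and the chemokine Ccl27a (580.1 ± 43.2 against 431 ± 57.9). None passed (limma adjusted p = 0.320 for each). limma called 0 of 16385 genes, edgeR 0, DESeq2 39 and limma with array weights 668. At an unadjusted p under 0.05 there were 1839 genes, 535 higher and 1304 lower, and 3036 without GFP control 11. Camera passed 19 of 37 lists, 8 higher and 11 lower, with 0 at an estimated correlation, and 12 without GFP control 10. Of the 19 calls, 13 with the striatal level, 14 with 3 tissue levels, 10 without 5 far libraries and 2 with array weights ended or turned.

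Stress under the ZBTB7A vector (ZBTB7A stress against ZBTB7A control, n = 5 each) gives the stress effect within that vector, while the interaction compares the vectors. Cartpt stood at 352 ± 104 after stress against 125 ± 44.9 normalized counts, Ntn1 at 566 ± 134 against 309.9 ± 55.4 and Zbtb7c, a relative of Zbtb7a, at 201 ± 49.6 against 122 ± 22. The lipid transfer protein Stard5 (0.86 ± 0.24, log2 and SE) and the mitochondrial ribosomal protein Mrpl30 (0.22 ± 0.07) also had small p, and none of these passed limma (adjusted p = 0.837 for Cartpt). DESeq2 called Cartpt alone. Striatal neuron genes were higher in 17 of 17 members by 0.82 (camera adjusted p = 1.0e-06 and adjusted p = 0.919 with an estimated correlation), with Penk at 1.02 and Rarb at 0.84. Their level differed with an exact permutation p = 0.206 (n = 5 and 5; adjusted over 37 lists, 0.991) and by -0.51, 0.77 and 0.85 within runs, and the mean was 1.30 without ZBTB7A control 6 and 0.50 without ZBTB7A control 15.

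Cytosolic ribosomal protein genes were higher after stress under ZBTB7A in 37 of 39 members, by 0.07 (camera adjusted p = 5.7e-05 and adjusted p = 0.997 with an estimated correlation), and by -0.02, 0.05 and 0.03 within runs. That call ended without ZBTB7A control 15 (0.03) or ZBTB7A stress 9 (0.03), and the mean was 0.12 without ZBTB7A control 6. Antigen presentation genes, with their regulators Nlrc5 at -0.76 and Ciita at -0.49, averaged -0.18 (18 of 22 below 0, camera adjusted p = 0.00125 and adjusted p = 0.967 with an estimated correlation). The call ended without ZBTB7A control 6 or 23 or ZBTB7A stress 25 or 26. Without ZBTB7A stress 17 that mean was -0.36. Interferon response genes averaged -0.08 (camera adjusted p = 0.0361 and adjusted p = 0.997 with an estimated correlation). This call ended without ZBTB7A control 6, 14, 23 or 24 or ZBTB7A stress 7, 25 or 26. It also ended with number run (-0.03). Immediate early genes averaged -0.14 (20 of 24 below 0, camera adjusted p = 0.00457 and adjusted p = 0.967 with an estimated correlation). This list call ended without ZBTB7A control 6, 23 or 24 or ZBTB7A stress 17 or 26. Genes of oligodendrocytes and myelin averaged 0.20 (23 of 24 above 0, camera adjusted p = 0.0325 and adjusted p = 0.997 with an estimated correlation). The list call ended without ZBTB7A control 14, 15 or 23 or ZBTB7A stress 7, 9 or 26, and the mean was 0.41 without ZBTB7A control 6. It also ended with number run (0.18) and turned with the striatal level (-0.06) and with 3 tissue levels (-0.0084). limma called 0 of 16385 genes, with edgeR at 0, DESeq2 at 1 and array weights at 0. There were 272 genes at an unadjusted p under 0.05, 1589 without ZBTB7A control 6, 165 without ZBTB7A control 15 and 153 without ZBTB7A stress 9. Camera passed 9 of 37 lists, 5 higher and 4 lower, 0 with an estimated correlation, and 4 without ZBTB7A stress 25. Of the 9 calls, 4 with the striatal level, 4 with 3 tissue levels, 4 without 5 far libraries and 1 with array weights ended or turned. The ribosomal, interferon and immediate early calls ended with either covariate, and without 5 far libraries the last 2 and the antigen call did.

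The interaction asks whether the stress response differed between vectors. Cartpt went from 232 ± 47.5 to 133 ± 53.4 normalized counts with stress under GFP and from 125 ± 44.9 to 352 ± 104 under ZBTB7A, a log2 interaction of 2.38 ± 0.40 (SE, limma adjusted p = 0.0976). It was the 1 gene under an adjusted p of 0.1. Ntn1 (1.40 ± 0.27), Kl (2.0 ± 0.44), Zbtb7c (0.94 ± 0.22) and the actin-binding protein Cald1 (0.61 ± 0.15) came next and did not pass. DESeq2 called Cartpt, Ntn1 and Kl. limma called 0 genes, edgeR 0 and limma with array weights 2068, while 1216 genes had an unadjusted p under 0.05, 924 above 0 and 292 below. limma called 79 genes without ZBTB7A control 6, Cartpt and Ntn1 without GFP stress 13, and Cartpt alone without GFP stress 22 or without ZBTB7A stress 17. Left-out libraries moved the number of genes at an unadjusted p under 0.05 to between 720 and 3406.

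Striatal and choroid plexus genes had the largest interactions of the lists. Striatal neuron genes averaged 2.33 (17 of 17 above 0, camera adjusted p = 5.7e-13 and adjusted p = 0.470 with an estimated correlation), with Isl1 at 4.61 ± 1.34, the transcription factor Six3 at 4.33 ± 1.54 and Drd2 at 3.34 ± 1.30, and 16 passed when adjusted over the list alone. Choroid plexus and ependymal genes averaged 2.26 (13 of 14 above 0, camera adjusted p = 5.4e-10 and adjusted p = 0.470 with an estimated correlation), with Clic6 at 3.84 ± 0.94 and Otx2 at 4.36 ± 1.18, and 9 passed when adjusted over the list alone. Oligodendrocyte and myelin genes averaged 0.84 (24 of 24 above 0, camera adjusted p = 5.4e-10 and adjusted p = 0.700 with an estimated correlation), with Mal at 1.05, and oligodendrocyte precursor genes 0.44 (14 of 14 above 0, camera adjusted p = 3.1e-05 and adjusted p = 0.470 with an estimated correlation), with Vcan at 0.84 and 1 member past when adjusted over the list alone. Blood genes averaged -2.0 (5 of 5 below 0, camera adjusted p = 6.7e-04 and adjusted p = 0.470 with an estimated correlation), with Hba-a2 at -2.07, and -1.33 without ZBTB7A control 23. With 3 tissue levels, Mal turned to -0.28 and the oligodendrocyte list to -0.40, and the precursor list turned by camera (0.03).

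Neuronal activity and synapse genes had interactions below 0. Immediate early genes averaged -0.37 (22 of 24 below 0, camera adjusted p = 3.0e-06 and adjusted p = 0.470 with an estimated correlation), with Btg2 at -0.69 ± 0.28 and Dusp6 at -0.62 ± 0.26. Presynaptic vesicle genes averaged -0.18 (22 of 26 below 0, camera adjusted p = 3.6e-04 and adjusted p = 0.765 with an estimated correlation), and -0.31 without ZBTB7A control 6. Postsynaptic density genes, with Camk2a at -0.36, averaged -0.11 (camera adjusted p = 0.00846 and adjusted p = 0.765 with an estimated correlation), -0.19 without GFP control 11. The list no longer passed without GFP control 1 (-0.04). With 3 tissue levels the presynaptic (0.25) and postsynaptic (0.10) lists, Camk2a and Gfap (from 0.67 ± 0.61) turned, and with the striatal level the presynaptic list did (0.07). Cytosolic ribosomal protein genes averaged 0.11 (35 of 39 above 0, camera adjusted p = 0.00117 and adjusted p = 0.765 with an estimated correlation). The list failed camera without GFP control 1 (0.07). It turned to -0.05 with the striatal level and to -0.17 with 3 tissue levels. Endothelial and mural cell genes, with Acta2 at 0.79, averaged 0.17 (camera adjusted p = 0.0208 and adjusted p = 0.765 with an estimated correlation). Their call ended without GFP control 19, GFP stress 3, 4 or 22 or ZBTB7A stress 25 or 26. Amine oxidation, adrenergic and serotonin receptor genes, with the serotonin receptors Htr4 at 1.76 ± 0.46, which alone passed when adjusted over the list alone, and Htr2c at 0.91 ± 0.31, averaged 0.51 (camera adjusted p = 0.0418 and adjusted p = 0.470 with an estimated correlation). That call ended without GFP control 11, GFP stress 13 or 21, ZBTB7A control 6, 15 or 24 or ZBTB7A stress 25 or with number run (0.48). This list shares 2 members with the striatal list and followed its level over the libraries, as given below. Extracellular matrix and scar genes averaged 0.29 (camera adjusted p = 0.0410 and adjusted p = 0.765 with an estimated correlation). The call ended without GFP control 10, 11 or 19, GFP stress 3, 12, 21 or 22, ZBTB7A control 6, 23 or 24 or ZBTB7A stress 17. Interferon response genes averaged -0.17 (camera adjusted p = 0.0291 and adjusted p = 0.765 with an estimated correlation). This call ended without GFP control 11, GFP stress 3, 12 or 13, ZBTB7A control 6, 23 or 24 or ZBTB7A stress 7, 25 or 26. Camera passed 13 of 37 lists, 8 above 0 and 5 below, 0 with an estimated correlation and 20 with array weights. Of the 13 calls, 6 with the striatal level, 7 with 3 tissue levels, 1 without 5 far libraries and 2 with array weights ended or turned. The oligodendrocyte, postsynaptic, extracellular matrix and amine calls ended with the striatal level, and the last 2 with 3 tissue levels.

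Across 16385 genes, which are not independent replicates, the virus effects with and without stress correlated at r = -0.26 (rho = -0.08), and 49.0% of genes had the same sign. The stress effects under the vectors correlated at r = -0.37 (rho = -0.26), with 42.3% of the same sign. The jackknife SE over libraries was 0.42 and 0.41, and r ran from -0.53 to -0.07 and from -0.60 to -0.17 as each library was left out, so neither r exceeded its spread. The effects within each pair share no library.

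**Figure D3:**
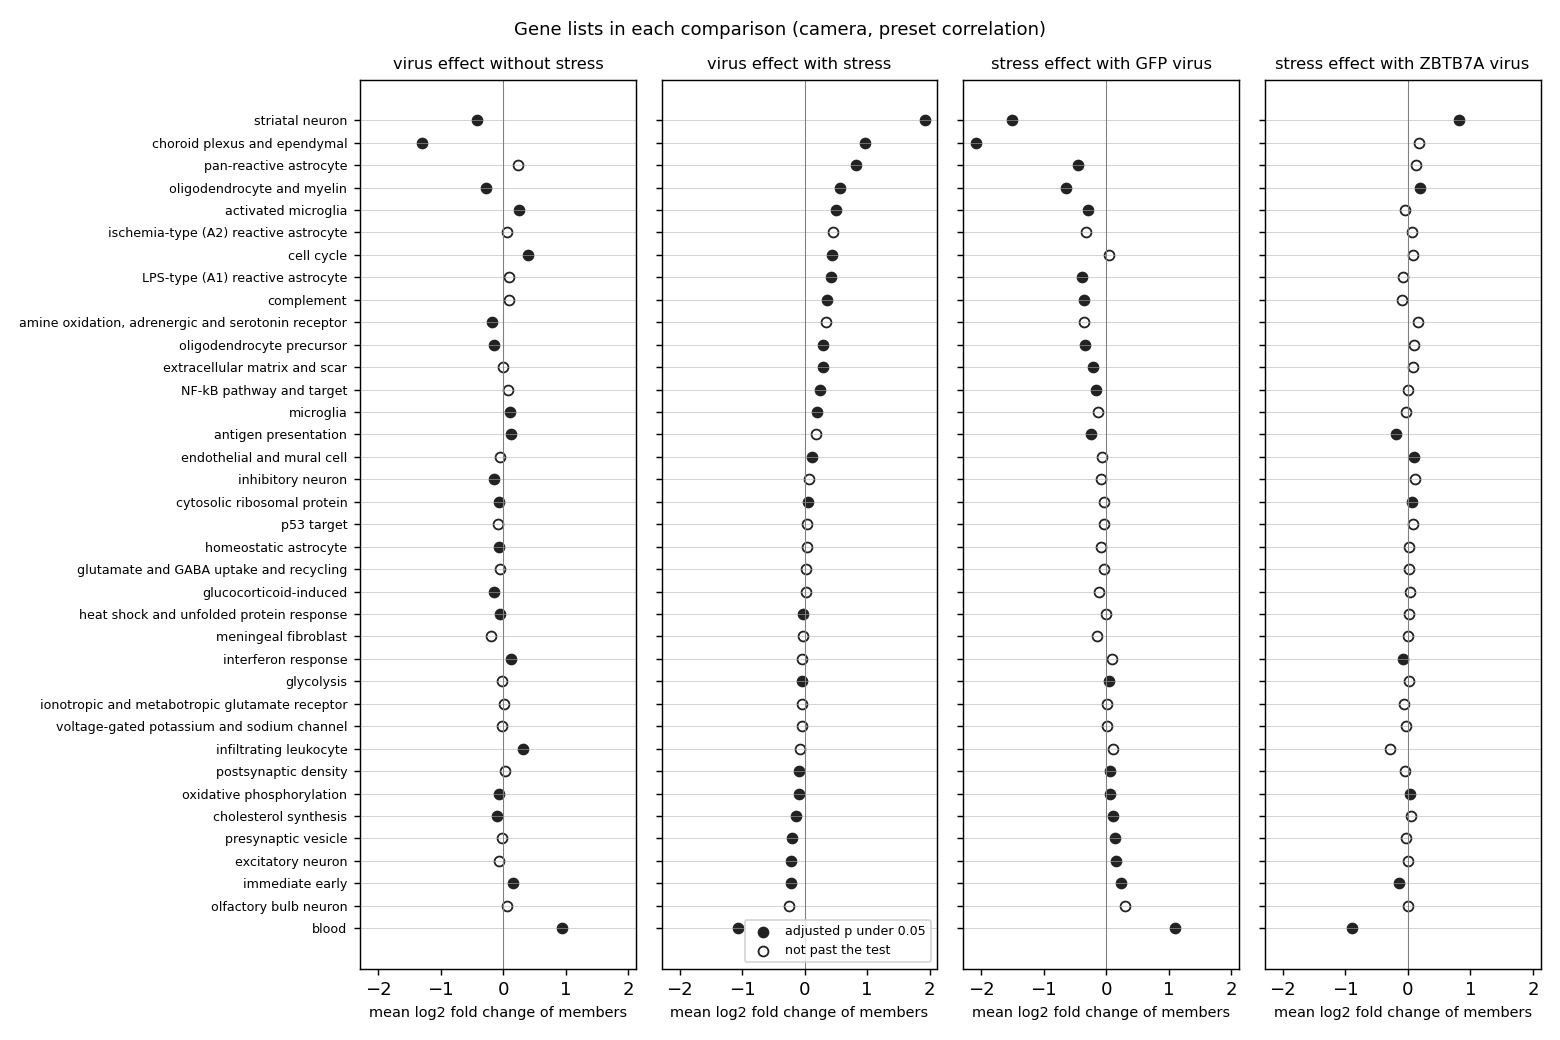
Mean log2 fold change of the members of each of 37 gene lists in the virus effect without and with stress and the stress effect with the GFP and the ZBTB7A virus, filled where camera passed at an adjusted p under 0.05 with its preset correlation (20, 23, 19 and 9 lists) and open where not. Striatal neuron genes lie at 1.92 in the virus effect with stress and at -1.51 in the stress effect with GFP virus, and with an estimated correlation 0 lists passed in any of them.

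Over the 23 libraries, other lists followed the level of striatal neuron genes, as 36 relations tested by permutation show. Oligodendrocyte and myelin genes rose with it at r = 0.73 (permutation p = 1.3e-04, adjusted p = 0.00144; rho = 0.63, adjusted p = 0.0104), with r at 0.62 without GFP stress 12 and 20 and 0.92, 0.50 and 0.78 within runs. Oligodendrocyte precursor genes had r = 0.72 (permutation p = 1.6e-04, adjusted p = 0.00144; rho = 0.67, adjusted p = 0.00461), with r at 0.58 without GFP stress 12 and 20 and 0.90, 0.74 and 0.59 within runs. Presynaptic vesicle genes fell as it rose at r = -0.73 (permutation p = 1.2e-04, adjusted p = 0.00144; rho = -0.72, adjusted p = 0.00180), with r at -0.67 without GFP stress 12 and 20 and -0.85, -0.62 and -0.68 within runs. For excitatory neuron genes the relation was r = -0.66 (permutation p = 4.9e-04, adjusted p = 0.00353; rho = -0.71, adjusted p = 0.00180), with r at -0.65 without GFP stress 12 and 20 and -0.81, -0.43 and -0.70 within runs. Choroid plexus and ependymal genes had r = 0.58 (permutation p = 0.00418, adjusted p = 0.020; rho = 0.62, adjusted p = 0.0110), with r at 0.45 without GFP stress 12 and 20 and 0.64, 0.42 and 0.62 within runs. Astrocyte reactivity genes had r = 0.34 (permutation p = 0.117, adjusted p = 0.191; rho = 0.33, adjusted p = 0.180), with r at 0.29 without GFP stress 12 and 20 and 0.87, 0.22 and 0.38 within runs, and the A1 and A2 lists r = 0.49 (permutation p = 0.0192, adjusted p = 0.0628) and 0.45 (permutation p = 0.0306, adjusted p = 0.0847). Amine oxidation, adrenergic and serotonin receptor genes followed it most closely, at r = 0.96 with r at 0.93 without GFP stress 12 and 20 and 0.99, 0.92 and 0.99 within runs, and their permutation p = 1e-05 (adjusted p = 3.6e-04) is the smallest these permutations can give. Of the 36 lists 10 had an adjusted p under 0.05 for r, the others being cholesterol synthesis genes at r = -0.59 (permutation adjusted p = 0.0179), cytosolic ribosomal protein genes at 0.57 (adjusted p = 0.020), cell cycle genes at 0.55 (adjusted p = 0.0252) and glutamate receptor genes at -0.51 (adjusted p = 0.0450). GFP stress 12 and GFP stress 20 were the farthest in striatal level, at -2.50 and -2.51.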

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

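The tests of why Zbtb7a was not raised, the leave-one-out bound on the striatal slopes, the share of other genes and the fit with recovered reads as a covariate were chosen only after the result was seen. The genes with an unadjusted p under 0.05 in the virus effect with stress may reflect how much neighbouring striatal tissue each dissection held. In the 10 unstressed libraries, 88.2% of 2618 such genes outside the striatal list had slopes on the striatal level of the sign this needs, against 65.2% of 13750 other genes. Their number was 545 with the striatal level, 635 with 3 tissue levels and 1015 without 5 far libraries. But the share above fell to 51.5% without ZBTB7A control 6, so tissue share and virus cannot be told apart. Whether abundant striatal members such as Ppp1r1b (2008 to 53879 normalized counts between libraries) moved together was not assessed. Of the 17 members tested, 2 are also in another list and 14 were at 10 or more normalized counts in all libraries, so the OFC may express them too, and the labels name microdissection but no sorting of cells. Depth as the cause is argued against, since 3380 genes had an unadjusted p under 0.05 with recovered reads as a covariate against 2635 without, while a response of OFC cells to ZBTB7A stays open as the biological explanation.

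That Zbtb7a was not higher in the libraries labelled ZBTB7A is the other pattern weighed. Virus labels exchanged between libraries stay open, since the highest library stood at 1.23 times the median and the counted gene would be flat under any labels if transgene reads are not counted. A rise of the counted gene hidden by the spread between libraries is argued against, since its upper 95% limit of the fold averaged over stress was 1.05. Transgene reads not counted as the mouse gene may account for it, since the fold of the counted gene was 0.965 and the species and sequence of the transgene are not given in the sources used here. Low expression or few infected cells in the dissected tissue was not tested.

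Other splits of the same libraries into groups of the same sizes, 100 for each comparison with the real one included, tested whether chance could give counts as large, in 15 tests not corrected for their number. For genes at an unadjusted p under 0.05, 3 splits gave as many for the virus effect with stress (real 2635, highest other 3636). More did so without stress (97; 284 and 3865), averaged over stress (28; 994 and 4980) or for stress with GFP (10; 1839 and 3283). More also did for stress with ZBTB7A (63; 272 and 3453) and the interaction (23; 1216 and 4357). For lists past camera chance was not excluded in any of the 6 comparisons, in the order virus without stress (16 splits; 20 and 27), virus with stress (7; 23 and 27), average (24; 17 and 27), stress with GFP (26; 19 and 30), stress with ZBTB7A (86; 9 and 23) and interaction (63; 13 and 26). The median of other splits was 12 to 14 lists in each, so the real counts for stress with ZBTB7A and the interaction were no higher than chance splits usually gave. With array weights few splits called as many genes for virus with stress (3; 2287 and 3835) or stress with GFP (2; 668 and 791). For the interaction the real split alone did (1; 2068 and 1356). By limma the real split called 0 genes in all 6 comparisons, as did most other splits (median 0), and only 3, 3, 3, 4, 1 and 3 splits called any. The highest of these few called 475, 545, 1690, 276, 158 and 1329 genes, which may point to a structure of some samples that does not follow the groups.

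A library far from the others of its group was found in 18 of 192 groups of values, where 9.6 were due by chance. In GFP control 10, Lcn2 stood at 2047 normalized counts (next highest 200.4) and C3 at 6416 (906), and the level of inhibitory neuron genes was -0.18 (0.07). In ZBTB7A stress 17, Lcn2 stood at 1761 (next 280.1), Cxcl10 at 78.0 (23.5) and C3 at 4438 (1348), with levels of 0.57 (0.04) for NF-kB genes, 0.057 (-0.01) for heat shock genes and 0.50 (0.10) for extracellular matrix genes. In GFP control 2, Nfkbia stood at 936 (next 479.9) and glucocorticoid-induced genes at 0.62 (0.10). Slc1a2 stood at 62718 in ZBTB7A control 15 (next 56738). Excitatory neuron genes stood at -0.77 in ZBTB7A control 6 (nearest 0.02). In ZBTB7A control 24 olfactory bulb neuron genes stood at 1.40 (next -0.25) and glutamate and GABA uptake genes at 0.046 (-0.02). Glutamate receptor genes stood at 0.22 in GFP control 11 (next -0.01). In GFP stress 12 potassium and sodium channel genes stood at 0.21 (next 0.02), and in GFP stress 13 extracellular matrix genes at 0.57 (next -0.06).

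A difference of the stress effect between vectors was found by camera for 13 lists, given here as mean log2 interaction, and 0 of them passed with an estimated correlation. Values above 0 were 2.33 for striatal neuron genes, 2.26 for choroid plexus and ependymal genes, 0.84 for oligodendrocyte and myelin genes, 0.51 for amine oxidation, adrenergic and serotonin receptor genes, 0.44 for oligodendrocyte precursor genes, 0.29 for extracellular matrix and scar genes, 0.17 for endothelial and mural cell genes and 0.11 for cytosolic ribosomal protein genes. Values below 0 were -2.00 for blood genes, -0.37 for immediate early genes, -0.18 for presynaptic vesicle genes, -0.17 for interferon response genes and -0.11 for postsynaptic density genes.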

How the results depend on the processing

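The tests with the striatal level, the levels of 3 tissue lists or the recovered reads as covariates, without 5 far libraries and with array weights for lists were chosen only after the result was seen. No paired analysis was possible because the groups share no replicate numbers. Counts of genes past limma stayed at 0 in all 6 comparisons with another pseudocount, filter, scaling or moderation, in edgeR, with number run as a covariate and under each covariate added later, and every named gene kept its sign with another pseudocount, no filter, TMM scaling and number run. The 76 list results followed here were limited to lists named in the report after their reversals had been seen, and counts over all called lists were also kept. Estimating the correlation between members ended all 76 and left 0 lists in each comparison. With number run as a covariate 9 of the 76 no longer passed camera, while over all called lists 3 ended for the virus effect without stress, 6 for stress with GFP, 3 for stress with ZBTB7A and 1 for the interaction. Recoveries of 66 to 83% (1.5-fold) and 87 to 93% (2-fold) came from genes simulated without correlation, so they set no detection limit here. The cause was not tested for any of the changes that follow.

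DESeq2 called 81, 7, 39, 1 and 3 genes for the virus effect with stress, the virus effect averaged over stress, stress with GFP, stress with ZBTB7A and the interaction. Array weights called 2287 for the virus effect with stress, 668 for stress with GFP and 2068 for the interaction. A fit of only the 2 groups compared called 2 for the virus effect with stress, and an adjusted p under 0.1 called 1 for the interaction. Leaving out each library in turn gave 0 to 3 genes for the virus effect with stress and 0 to 79 for the interaction. It gave 12 to 20 lists for the virus effect without stress, 12 to 24 for stress with GFP and 4 to 13 for stress with ZBTB7A. With the striatal level as a covariate, 7 lists passed for the virus effect with stress and 10 for stress with GFP, and with 3 tissue levels 11 for the virus effect with stress. Without 5 far libraries 14, 6 and 12 lists passed for the virus effect with stress, the average and stress with GFP, and with array weights 20 did for the interaction. These counts include the lists that supplied the covariate or chose the libraries, which lose their difference by construction, so those lists and their members were not followed there. Over leave-one-out fits, the virus effect without stress ran from -0.11 to 0.042 for Zbtb7a, -0.093 to 0.56 for Gfap, -0.068 to 0.075 for Slc1a3, -0.37 to 1.31 for C3 and -0.14 to 6.3e-04 for cholesterol synthesis genes. Stress with GFP ran from -0.031 to 0.12 for Zbtb7a and -0.27 to 0.014 for NF-kB genes. Stress with ZBTB7A ran from -0.024 to 0.039 for Zbtb7a, -0.23 to 0.22 for Gfap and 0.030 to 0.41 for oligodendrocyte genes, and the interaction of Zbtb7a from -0.11 to 0.043.

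Of 37 list results that turned under a setting below, 15 passed camera in the other direction. Signs turned in the virus effect without stress in edgeR (Lcn2 -0.12 and C3 -0.36), in DESeq2 (Lcn2 -0.13 and C3 -0.36) and with array weights (Gfap -0.22, Slc1a3 -0.069 and C3 -0.17). In the lists they turned for microglia genes (-0.040) and cholesterol synthesis genes (0.046) with array weights, and for cholesterol genes without 5 far libraries (6.3e-04). In the virus effect with stress, leaving out 5 far libraries turned ribosomal (-0.0090) and cell cycle genes (-0.043). With the striatal level as a covariate the virus effect with stress turned for the lists oligodendrocyte -0.045, presynaptic 0.0067, ribosomal -0.082 and cell cycle -0.15 and for Nfkbia -0.0057. Under that covariate stress with ZBTB7A turned for oligodendrocyte genes -0.061 and Gfap -0.16, and the interaction for presynaptic genes 0.074 and ribosomal genes -0.049.

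With the levels of all 3 tissue lists as covariates, 25 of the list results and 24 of the gene results turned, lists in the direction of the camera test, which for glucocorticoid-induced, postsynaptic and oligodendrocyte precursor genes differed in sign from the mean. The virus effect without stress turned for homeostatic astrocyte genes 0.016, oligodendrocyte genes 0.26, glucocorticoid-induced genes -0.039, ribosomal genes 0.060, Enpp2 0.070 and Aqp4 0.089. The virus effect with stress turned for the lists oligodendrocyte -0.13, excitatory 0.051, presynaptic 0.049, postsynaptic -9.7e-05, ribosomal -0.11 and cell cycle -0.20, and for Mal -0.030, Trf -0.040, Opalin -0.050, Olig2 -0.037, Snap25 0.0012, Stx1a 0.010, Camk2a 0.040, Bdnf 0.0032, Nptx2 0.011 and Nfkbia -0.027. Stress with GFP turned for the lists pan-reactive 0.27, A1 0.041, oligodendrocyte 0.39, oligodendrocyte precursor -0.0075, excitatory -0.23, NF-kB 0.15, complement 0.094, presynaptic -0.21 and postsynaptic -0.13, and for Zbtb7a -0.029, Fezf2 -0.10, Nrgn -0.034, Mal 0.36, Syp -0.20, C4b 0.61 and Gfap 0.47. Stress with ZBTB7A turned for oligodendrocyte genes -0.0084 and Gfap -0.069. The interaction turned for the lists oligodendrocyte -0.40, oligodendrocyte precursor 0.029, presynaptic 0.25, postsynaptic 0.10 and ribosomal -0.17, and for Zbtb7a 0.041, Mal -0.28, Camk2a 0.18 and Gfap -0.54.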

Other observations

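The tests of genes and gene lists between the runs of library numbers were chosen only after the result was seen. With group in the model, limma called 181 genes between the 3 number runs at an adjusted p under 0.05, 96 of them higher and 85 lower in the second run than in the first, and 3613 genes had an unadjusted p under 0.05. Cytosolic ribosomal protein genes, which encode the protein part of the ribosome, had a mean log2 difference of -0.17 (camera adjusted p = 6.5e-15 and adjusted p = 0.731 with an estimated correlation) between the second run and the first, with 37 of 39 members below 0. In the third run they differed from the first by -0.12 (camera adjusted p = 2.5e-13 and adjusted p = 0.566 with an estimated correlation). Meningeal fibroblast genes, which mark the covering of the brain, were higher in the second run by 0.52 (camera adjusted p = 0.0109 and adjusted p = 0.731 with an estimated correlation) and in the third by 0.61 (camera adjusted p = 1.9e-05 and adjusted p = 0.566 with an estimated correlation). Olfactory bulb neuron genes, which mark the neighbouring olfactory bulb, were higher in the third run by 0.80 (camera adjusted p = 0.00261 and adjusted p = 0.566 with an estimated correlation) but differed by -0.23 (camera adjusted p = 0.0326 and adjusted p = 0.731 with an estimated correlation) in the second. Striatal neuron genes differed from the first run by -0.99 (camera adjusted p = 8.4e-05 and adjusted p = 0.731 with an estimated correlation) in the second and by -0.83 (camera adjusted p = 1.8e-06 and adjusted p = 0.566 with an estimated correlation) in the third. Oligodendrocyte and myelin genes differed by -0.42 (camera adjusted p = 1.6e-07 and adjusted p = 0.566 with an estimated correlation) in the third run. For microglia genes that difference was -0.24 (camera adjusted p = 1.9e-07 and adjusted p = 0.566 with an estimated correlation). The labels do not say what the numbers stand for, and each run holds libraries of all 4 groups.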
